A study of Eisenia fetida with 4 samples.

How the data were processed

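Labelled cRNA was made from 0.5 ug of RNA of the pool with a single dye, Cy3, per the labels' protocols. The arrays were custom Agilent 60-mer arrays, and each was scanned at both gains, so the array number pairs the scans of the same physical array. Scans were made with a GenePix 4200A at 532 nm and 5 um pixels, and read with GenePix Pro 6.1.0.4 without normalization and with local background, per the file headers. The deposited intensity values are the spot median, spot mean, local background and background SD of each spot on a linear scale, per the file headers. The percent of saturated pixels per spot is also the value deposited, from the image software named in the file headers. The authors' deposited values for the whole series held the intensity of the spot median minus the local background, on a linear scale without centring or normalization. They were checked against the scanner values and were equal at all 243504 spots of array 1 and at 243503 of array 2, where 1 control cell was blank. Their medians per scan were 22.0 and 101 for array 1 and 22.0 and 104 for array 2, at gains 400 and 500. Recorded laser power was 2.40 at gain 400 and 2.39 at gain 500.

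Samples were grouped by the gain in their titles. Median spot signals of the test probes were 63.0 and 65.0 at gain 400 and 227 and 238 at gain 500, on arrays 1 and 2, above median local backgrounds of 44.0, 45.0, 139 and 145. Detection used the background-subtracted spot median against the mean plus 2 SD of 602 negative control spots. The gain ratio was the median ratio of background-subtracted medians. A variant over all test probes could use only those with a positive signal in both scans, 211109 on array 1 and 208060 on array 2.

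For the comparison of gains, spot medians were corrected with normexp (offset 50) on all spots, control spots were left out, and log2 signals were quantile normalized over 4 scans. Gain 500 was compared with gain 400 by lmFit and eBayes in limma 3.58.1 under R 4.3.3, with data.table for reading, at a Benjamini-Hochberg adjusted p of 0.05. The fit was tested on simulated data with 200 changed probes among 241399, all picked among the brightest probes. Noise was drawn independently for each scan. At a log2 shift of -1 the fit recovered 36.0% of the changed probes, and 62.0% with the replicate block. At -2 and -4 it recovered 100%. Recovery of dimmer probes was not tested, nor that of a saturation shared by the brightest probes. False calls numbered 11, 9 and 16. Deviations from the gain mean correlated at 0.218 between scans of 1 array, across all test probes. Of these, 148184 had a signal of up to 30 at gain 400. Brighter probes were paired more closely by array. For signals of 1000 to 3000 the log2 differences had an SD of 0.28 between arrays at gain 400 and 0.06 between gains. The simulated noise did not carry this pairing. Other values were computed in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. Shares were compared between gains by exact two-sided permutation tests, unpaired as fixed beforehand and, added later, paired by array. The order of spike-ins was tested by a two-sided permutation test with 100000 resamples, and by an exact one over the 7 detected spikes.

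The main settings, the variants not described as added later, and the rule for named items were fixed before the data were examined. The rule named every spike-in, and, per gene list or among probes past the threshold, the brightest or most changed ones. It named no test probe, because none passed the threshold and gene names were not used here. The planned tests of gene lists and of the spread among probes of 1 transcript were not run for the same reason. Other alternatives changed the background correction, normalization, spot statistic, probe filter, saturation rule and detection limit, or left out a scan. With 2 arrays per gain, neither a test for outlying scans nor other splits of the scans applied.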

Results

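The arrays measured transcripts of the earthworm Eisenia fetida, a composting worm widely used in soil toxicology. RNA from adults, juveniles and cocoons was combined into 1 pool, so every array carried the same mixture of 3 life stages. The pool was hybridised to 2 arrays of 1 test design, out of 4 test designs made with probes in both orientations; the title of this one calls it sense. Each array carried 241399 test probes of 60 bases, each printed once, with 602 negative control spots and 1503 positive control spots. Each array was scanned at photomultiplier gains of 400 and 500, which gave 4 scans in 2 groups of 2 arrays. Because 1 pool was used, the spread between arrays was technical, and p-values for the comparison of gains measure only technical spread. Other p-values below are taken across spikes, control spots or probe positions and describe these arrays only. The number of arrays limited the precision, and life stages could not be compared. The files give the test probes serial numbers without gene names, so the transcripts below are described as probe sets.

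The first question was how many probes gave a signal above the negative controls. A probe was called detected when its background-subtracted signal exceeded the mean plus 2 SD of the negative controls of the same scan. All 602 negative control spots share the control name (-)3xSLv1. The limit therefore does not cover differences in unspecific signal between probes, and a detected probe need not have bound its own transcript. At gain 400, 41.4% ± 1.92 (SD, n = 2) of the test probes were detected, 42.8% on array 1 and 40.04% on array 2. At gain 500 the share was 41.1% ± 0.614 (SD, n = 2), with 41.6% on array 1 and 40.7% on array 2. Both arrays detected 87376 probes (36.2%) at gain 400 and 87104 (36.1%) at gain 500. A set of 80778 probes (33.5%) was detected in all 4 scans, and 116104 probes (48.1%) in none of them. Of the negative controls, 10 and 5 of 602 exceeded the limit on arrays 1 and 2 at gain 400, and 11 and 8 at gain 500. The share depended on the limit: without subtraction of the local background it was 51.2% at gain 400, a setting chosen after the data were seen, and against the local background plus 2 SD it was 31.2%.

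The second question was what the higher gain changed in detection. From gain 400 to gain 500 the detected share moved by -1.20 percentage points on array 1 and by 0.657 on array 2, so the arrays went opposite ways. The exact two-sided permutation test gave p = 1.00, both over the 4 scans and with the scans paired by array; the smallest p possible is 0.333 unpaired and 0.500 paired. Both arrays detected 1724 probes at gain 400 that neither detected at gain 500, and 1528 probes the other way round. The size and order of these counts depended on the limit. They were 894 and 987 at 3 SD, and 1626 and 933 against the local background plus 2 SD. In settings chosen after the data were seen, they were 941 and 1255 without subtraction and 1747 and 1679 with median absolute deviations. The SD of the negative controls was 9.82 ± 0.929 (SD, n = 2) intensity units at gain 400 and 47.6 ± 2.91 at gain 500, a ratio of 4.85. The signal therefore had to clear a limit of 28.7 ± 1.13 intensity units at gain 400 and of 136 ± 5.40 at gain 500.

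Test probes brightened by a near-constant factor between the gains. Over probes detected and free of saturated pixels in both scans, gain 500 over gain 400 was 4.97-fold ± 0.0735 (SD, n = 2), from 87856 probes on array 1 (4.91-fold) and 85052 probes on array 2 (5.02-fold). Probes were also grouped by their signal on the other array, a grouping chosen after the data were seen. On array 1 the median ratio was 4.74-fold for signals of 30 to 100, 4.96-fold for 300 to 1000 and 5.01-fold for 3000 to 10000. It was 3.86-fold for 10000 to 30000, where 78.5% of the probes were saturated at gain 500, and 1.15-fold above 30000, where 99.2% were. On array 2 the last 2 classes gave 4.44-fold and 1.29-fold, with 65.0% and 100% of the probes saturated.

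**Figure D1:**
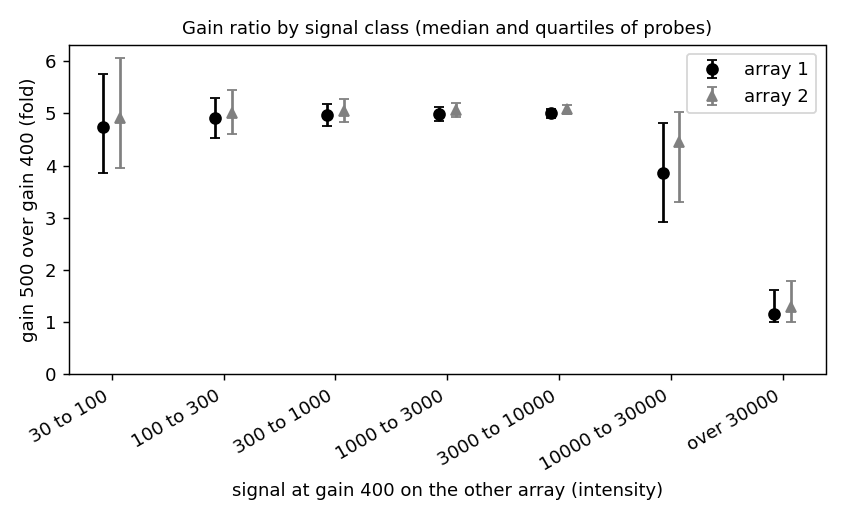
Ratio of gain 500 to gain 400 signal (fold, vertical axis) for test probes grouped by their gain 400 intensity on the other array (horizontal axis), with points for the median and bars for the quartiles of the probes of each array. The medians lie between 4.74 and 5.08 up to an intensity of 10000 and fall to 1.15 and 1.29 above 30000.

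Saturation was higher at gain 500 on both arrays. A probe was called saturated when at least 50% of its pixels were at the scanner's maximum. At gain 400 this held for 196 probes on array 1 and 182 on array 2, or 0.0783% ± 0.00410 (SD, n = 2) of the test probes. At gain 500 it held for 1202 and 1162 probes, or 0.490% ± 0.0117 (SD, n = 2), 6.25 times the share at gain 400. The share was higher by 0.417 percentage points on array 1 and by 0.406 on array 2, changes larger than the spread between arrays. With the scans paired by array, the exact two-sided permutation test gave p = 0.500, the smallest that 2 pairs allow. The exact permutation test fixed beforehand, which takes the scans as unpaired, gave p = 0.333, also the smallest possible, so neither could pass 0.05. Both arrays were saturated for 177 probes at gain 400 and for 1141 at gain 500.

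The third question was whether any probe departed from the common factor once the scans had been brought to the same distribution. The limma test, with quantile normalized log2 signals and Benjamini-Hochberg adjustment over 241399 probes, called 0 probes at an adjusted p of 0.05. At an unadjusted p under 0.05 it counted 11183, less than the share of 0.05 that tests without any departure would give. The log2 differences ran from -1.92 to 1.15. Quantile normalization can also take out a change of ratio that the brightest probes share. The 0 is therefore not a count of probes that follow the common factor: above 30000 the median ratio was 1.15-fold on array 1 and 1.29-fold on array 2. With the array number as a replicate block the test also called 0 probes, with 12224 at an unadjusted p under 0.05, close to a share of 0.05. The call rested on the normalization. Median centring of each scan, which moves the median of all probes to 0.05 on the log2 scale, called 194 probes. All 194 were lower at gain 500 after centring, by a median log2 of -1.50. All 194 had saturated pixels on both arrays at gain 500, and 176 of them stood at the scanner's maximum in all 4 scans. Those 176 read the same maximum at both gains, so their lower value was set by the centring and was not a drop in spot signal. With 1 background value per scan, a setting added after the data were seen, median centring called 107886 probes, 78655 higher and 29231 lower. The fit limited to the 80778 probes detected in all 4 scans called 153, of which 52 were higher and 101 lower.

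The spike-in controls, synthetic RNAs of the labelling kit, spanned the range of the scanner. The order of their amounts was taken from general knowledge of the kit, was not given in the sources used here and was not checked. Over the 7 spikes above the detection limit in at least 3 scans, a choice made after the data were seen, the signal rose with that order in each of the 4 scans. Spearman's rho across these spikes was 1.00 at both gains, with an exact two-sided permutation p of 0.000397 that Benjamini-Hochberg adjustment over both tests left the same. The test fixed beforehand took all 10 spikes and the mean of both arrays, and gave rho 1.00 at gain 400 and 0.988 at gain 500 (permutation p = 2e-05 each, the smallest the resamples can give, and the same after adjustment). It counts the 3 dimmest spikes, which lay below the limit in all 4 scans and have no order there. On array 2 at gain 400 (+)E1A_r60_3 read 12.5 and (+)E1A_r60_a104 read 12, against the order, and on array 1 (+)E1A_r60_a104 and (+)E1A_r60_a107 both read 15.5. At gain 400 the brightest spike, (+)E1A_r60_1, gave 30074 ± 387 (SD, n = 2) intensity units. The next, (+)E1A_r60_n9, gave 7455 ± 467, and (+)E1A_r60_n11 gave 3671 ± 100.4. Below these, (+)E1A_r60_a97 gave 1035 ± 48.4, (+)E1A_r60_a22 gave 331 ± 19.8 and (+)E1A_r60_a20 gave 78.0 ± 5.66. The signal of (+)E1A_r60_a135 was 31.0 ± 3.54, above the limit in 3 of 4 scans. The last 3 were above it in 0 scans: (+)E1A_r60_a107 gave 16 ± 0.707, (+)E1A_r60_a104 gave 13.8 ± 2.47 and (+)E1A_r60_3 gave 12.3 ± 0.354, against a median of 9.75 ± 0.354 for the negative controls. At gain 500 the brightest spike was saturated: it exceeded (+)E1A_r60_n9 by 1.76-fold ± 0.0361 (SD, n = 2), against 4.04-fold ± 0.201 at gain 400. The step from (+)E1A_r60_n11 to (+)E1A_r60_n9 was 2.03-fold ± 0.0716 at gain 400 and 2.05-fold ± 0.0198 at gain 500, a difference within the spread of the arrays.

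**Figure D2:**
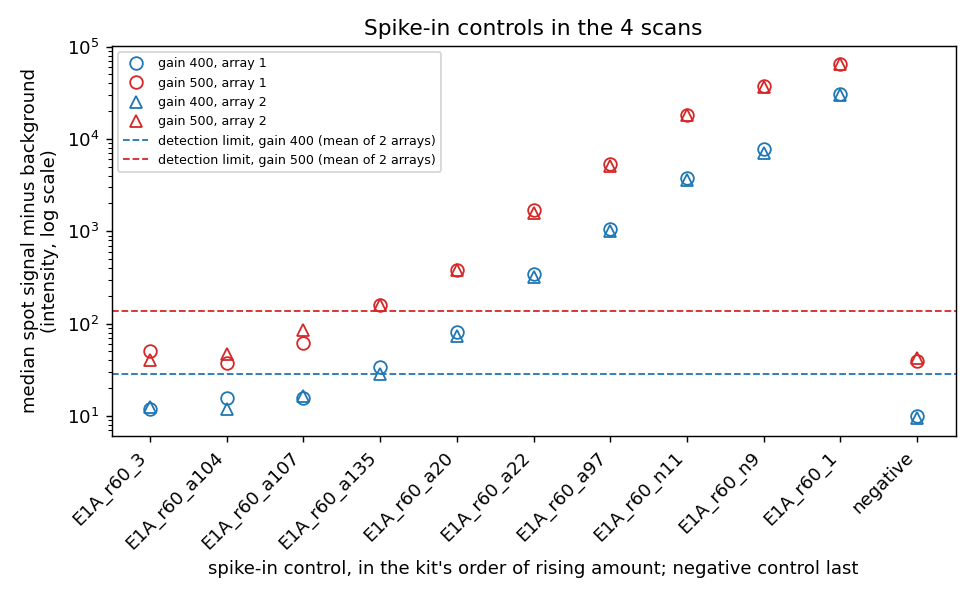
Median background-subtracted intensity (log scale, vertical axis) of the 10 spike-in controls and of the negative controls (horizontal axis) in each of the 4 scans, with dashed lines for the mean detection limit at each gain. The 3 spikes of lowest amount lie below the limit at both gains, and (+)E1A_r60_1 reaches 65368 at gain 500.

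The arrays also hold control families whose names differ in a last number, which the files do not define; they were chosen for description after their values were seen. At gain 400, DCP_1_1, DCP_1_2, DCP_1_4 and DCP_1_7 gave 81.2% ± 1.02, 55.1% ± 0.488, 28.9% ± 0.0404 and 16.6% ± 0.224 (SD, n = 2) of the signal of DCP_1_0. DCP_1_11 was below the detection limit in all 4 scans. In a dimmer family, DCP_22_2, DCP_22_4 and DCP_22_6 gave 68.2% ± 0.219, 33.2% ± 0.804 and 15.8% ± 1.14 of DCP_22_0, and these 3 were above the limit in all 4 scans. DCP_22_7 was above it in 3 scans and DCP_22_9 in 1, so their shares, 7.69% ± 0.221 and 7.64% ± 2.83 at gain 400 and 9.47% ± 0.563 and 5.27% ± 1.97 at gain 500, lay near background. In the dimmest family, where DCP_20_0 read 87.0 ± 12.7 intensity units, DCP_20_1, DCP_20_3 and DCP_20_5 gave 95.4% ± 15.3, 75.8% ± 14.3 and 42.3% ± 12.7 of it. At gain 500, where this family was far from saturation, the shares were 89.99% ± 21.7, 69.3% ± 14.6 and 27.5% ± 3.17, and DCP_20_5 was above the limit in 3 of 4 scans. DCP_20_7 and DCP_20_9 were below the limit in all 4 scans, so their shares, 17.2% ± 8.05 and 27.7% ± 9.75 at gain 400 and 27.0% ± 1.19 and 18.3% ± 4.28 at gain 500, have no order.

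The last question was how well the arrays repeated each other. After normexp correction and quantile normalization, the log2 difference between the arrays had an SD of 0.31 over the test probes at both gains, and 94.3% of the probes at gain 400 lay within 1.5-fold. Between the gains of 1 array the SD was 0.28 on each array, and both spreads differed with signal. In classes of signal chosen after the data were seen, probes below 30 gave 0.33 between the arrays at gain 400 against 0.32 between the gains of each array. Probes of 300 to 1000 gave 0.26 against 0.09 on each array, and probes of 1000 to 3000 gave 0.28 against 0.06. The SD scaled from the median absolute deviation, which outlying probes move little, was 0.12 between arrays at gain 400 and 0.06 between gains for background-subtracted signals of 1000 to 3000. Above 10000, where saturation at gain 500 sets in, it was smaller between arrays: 0.10 at gain 400 against 0.46 and 0.38 between the gains of arrays 1 and 2 for 10000 to 30000, and 0.06 against 0.32 and 0.48 above 30000. The plain SD of the same signals went the other way. It was 0.87 between arrays at gain 400 against 0.42 and 0.37 between gains for 10000 to 30000, and 0.97 against 0.42 and 0.41 above 30000. These values rested on the processing: with local background subtraction floored at 1, the SD between arrays at gain 400 was 1.98 and 54.9% of the probes lay within 1.5-fold. With median centring the order turned round at gain 400, with an SD of 0.25 between arrays against 0.54 and 0.34 between the gains of arrays 1 and 2. Over the 87376 probes detected on both arrays at gain 400, the SD between arrays was 0.20. Across probes, which are not independent replicates, Spearman's rho between the arrays was 0.790 at gain 400 over all test probes and 0.973 over the detected ones.

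Probes that disagreed between the arrays lay close together. At gain 400, 431 test probes differed by over 4-fold with signals floored at 20; this limit was chosen after the data were seen. Of these, 419 were higher on array 2 and 12 on array 1, and 402 (93.3%) lay in the last twelfth of the rows, from row 837 on. Of the 12 higher on array 1, 7 lay in those last rows, all within rows 857 to 861 and columns 31 to 36. At gain 500, 381 of the 431 differed by over 4-fold in the same direction. No spot of any scan carried a flag.

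**Figure D3:**
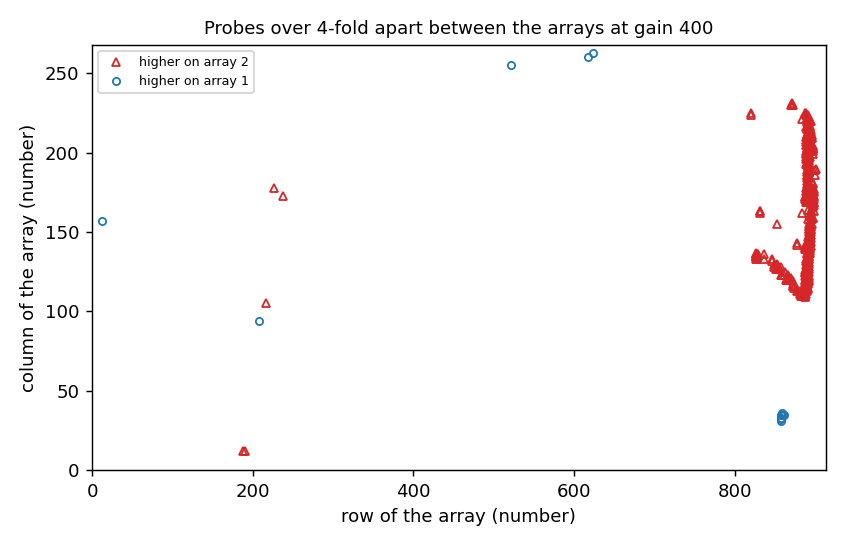
Position on the array (row number, horizontal axis; column number, vertical axis) of the 431 test probes that differed by over 4-fold between the arrays at gain 400, with triangles for probes higher on array 2 and circles for probes higher on array 1. Most triangles follow a narrow curved line in the last rows.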

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

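All control sets not used in the comparisons were set against the detection limit, and the set below was picked out by its values. ETG05_36762, a control set of 40 spots, gave 85.0 ± 5.66 (SD, n = 2) intensity units at gain 400 and 421 ± 48.1 at gain 500. It was above the limit set by the negative controls in 4 of 4 scans. The other 12 sets with the same prefix gave 8.25 to 13.8 at gain 400 and were above the limit in none of the 4 scans. The same held for all 12 RC sets and all 4 eQC sets. The files do not say what the set was designed to, and no explanation was tested.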

How the results depend on the processing

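Settings named here as added were chosen after the data were seen. Alternatives left a value within its spread or limit in 31 cases and moved it in 29. The 31 include cases whose outcome was fixed in advance. With 2 arrays, each lies within 1 SD of their mean by arithmetic, so leaving out 1 array could not move a share or the gain ratio. The fit on the authors' deposited values repeated the one with floored subtraction. The main count of 0 called probes became 194 under median centring, 222529 without normalization and 153 with probes detected in all 4 scans. With 1 background value per scan and median centring (added) it was 107886 (78655 higher, 29231 lower). Without normalization all calls were higher, as the gain factor is then not removed, and the median of all probes moved to 1.55 on the log2 scale. Saturation was examined for the 194 calls under median centring only. The cause of the 153 and of the 107886 calls was not tested. The paired fit, with the replicate block, kept 0 calls, as did each fit without 1 scan (0 to 0), where the lone scan is assumed to vary like the others. The gain ratio was 4.50 without background subtraction and 4.89 over all probes with positive signal (4.91 to 5.02 without 1 array). Saturated shares were 0.124% and 0.673% with any saturated pixel (gains 400, 500). Detected shares were 34.3% and 34.4% at 3 SD, 31.2% and 30.2% against the local background, 51.2% and 51.6% without subtraction (added), and 41.9% at gain 500 with median absolute deviations (added). The SD between arrays was 0.25 and 0.47 with median centring, 1.98 and 2.00 with floored subtraction, 0.37 and 0.37 with spot means, 0.20 and 0.21 over detected probes, and, added, 0.29 and 0.30 without the last rows, 0.22 and 0.21 without background correction and 0.28 and 0.27 with 1 background value per scan; the cause was not tested. Leaving out flagged spots moved nothing, as none carried a flag. Gene list detection and the spread of probes within a transcript were not run, as gene names were not used here. Signal over background limits detection: 3 spikes lay below the limit.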

Other observations

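Tests chosen only after their result or a related one was seen were those of the local background, of the spot grid and of the control spots along the line, and the first test of chance placement; the gathering in the middle rows was tested after the counts of calls by band of rows were seen. No biological explanation was tested for any pattern below, since all scans carried 1 RNA pool.

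The detected share of test probes varied with the serial number of the probe. In blocks of 10000 numbers, the share detected on both arrays at gain 400 ran from 29.1% (60001 to 70000) to 46.4% (230001 to 240000). The hypothesis that neighbouring numbers share a transcript predicted similar signals at a step of 1, and the rank correlation across probes was 0.0402. Pairs more than 20 rows or columns apart, which were nearly all consecutive pairs, gave 0.0403. This argues against closeness on the array as the source of even that value. Pairs far apart in columns can still share a band of rows, so the test cannot decide on differences between bands.

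A hypothesis that bright spots lend light to their neighbours was tested on the negative controls. Those beside a spot of the top 1% were dimmer by 2.5 intensity units on array 1 and differed by -1.0 on array 2 at gain 400 (one-sided permutation p = 0.928 and 0.650). This argues against lent light that remains after subtraction of the local background. Light that also reached the local background would be subtracted, so the test cannot decide on it.

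Probes that left the common gain ratio under median centring gathered in the middle rows. All of them (100%) had saturated pixels at gain 500 on both arrays, and 0% lay below detection at gain 400, so saturation may account for them and dim signal does not, although only 12.8% of the 1514 probes with saturated pixels on both arrays at gain 500 were called. With the rows cut into 4 equal bands, the band with most calls had 2.32 times the share of the one with fewest, past the bound of 2 set beforehand for an effect of position, yet every probe at the maximum in all 4 scans was called in every band. Those 176 probes lay 120 to 56 in the middle against the outer bands (exact binomial p = 1.15e-06, which decides nothing, as these probes prompted the test), but 943 other probes, saturated on both arrays at gain 500 and on neither at gain 400, lay 526 to 417 (exact two-sided binomial p = 0.000383, or 0.00276 with 18 probes, the number of remaining calls, taken out of the middle), which argues against chance placement. The spike-in spots were brighter in the middle by 0.42 (array 1) and 0.29 (array 2) on the log2 scale at gain 400, past the bound of 0.2, and stronger hybridisation in the middle rows is a candidate explanation.

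Detection rested on the local background. The SD of the negative controls without subtraction was at most 0.524 of the SD after it, against a bound of 0.5 set for every scan. Array 1 met the bound (0.402 and 0.411) and array 2 did not (0.506 and 0.524), so by that bound noise of the local background stays open. Subtraction still widened the spread on every scan. The local backgrounds of these spots had SDs of 8.52 and 40.6 on array 1 and 10.4 and 48.5 on array 2, at gains 400 and 500. Their spot medians had SDs of 3.68 and 18.7 on array 1 and 5.30 and 26.0 on array 2. The rank correlation of spot and background reached 0.238 on array 2, between the bounds for real unevenness of the slide. On array 1 it was at most 0.0377, which argues against unevenness there; reading the arrays apart was decided after the values were seen.

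The discordant probes of array 2 form a line. A shifted spot grid would move signals both ways, and 98.3% of the discordant probes in the last rows were higher on array 2. A fluorescent mark, such as a scratch or fibre, was first tested on the 14 negative controls within rows 854 to 899 and columns 111 to 223: they lay 0.682 SD above the others (95% bootstrap interval 0.195 to 1.07), under the bound of 1 SD set beforehand, though only 7.15% of the probes in that area were discordant. After the map was seen, 10 control spots along the line itself were tested, and their median at gain 400 was 42.0 on array 2 (limit 29.5) and 14.0 on array 1 (limit 27.9). On array 2 the spots ran from -2.0 to 445, and 5 of the 10 exceeded the limit against 0 on array 1. At gain 500 their median was 220 on array 2 and 63 on array 1, and 6 against 0 exceeded the limit. The median at gain 400 thus met the bound written for this test. Its 95% bootstrap interval, 16 to 92, includes the limit. Asking that the interval clear the bound, in both tests of a mark, was decided after the results were seen. By that rule neither test decides, and a mark stays open.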
